A study of Mus musculus with 12 samples.

How the data were processed

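RNA of mouse embryonic stem cells (4 samples labelled Tbx3-high, 4 labelled Tbx3-low) and of mouse induced pluripotent stem cells (2 labelled Tbx3-null, 2 labelled wild type) was measured on 12 Agilent one-colour arrays with 55681 probes. Per the labels' protocols, total RNA was extracted with RNeasy kits and Cy3 was attached to 50 ng per sample by the Low Input Quick Amp Kit. Per the file headers, Agilent Feature Extraction 10.7.3.1 made the intensity of each spot, a processed signal with background subtracted and spatial trends removed but not scaled between arrays, and placed the probes on mm9. Per the file headers, the mean spot intensity and the median local background intensity were stored unscaled beside it. The deposited series table holds log2 values whose method is not given in the sources used here. Its columns correlated with the log2 mean spot intensity at r of at least 0.9988, its medians were 6.61 on the mESC arrays and 6.58 to 6.59 on the iPSC arrays, and sorted columns differed by at most 0.168 within the mESC and 0.134 within the iPSC arrays. How its values were scaled and whether background was removed stay unknown, so it served as an alternative only. How Tbx3-high and Tbx3-low cells were separated, which part of Tbx3 the null allele lacks and whether arrays stand for separate cultures are not given in the sources used here.

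The values analysed were log2 of the processed signal minus each array's 75th percentile over probes that are not controls. Spots with an outlier mark of the scanner software were set to missing, and spots of 1 probe were averaged. A probe counted as well above background on an array when all its unmarked spots there were. A group counted as dim when, on each of its arrays, fewer of the probe's spots were well above background than not. A probe entered a comparison when it was well above background on every array of at least 1 of the groups compared; 37072 probes met this in at least 1 of the 4 groups. Each gene was represented by its probe with the highest mean signal over the 12 arrays. Names came from a RefSeq gene table (GRCm38, used for names and neighbours only): 27656 probes matched by accession, 3401 by symbol and 317 by synonym, 1764 kept the file's name and 22543 without a name stayed out of the gene counts. A synonym was accepted only where its gene lay on the probe's chromosome, which refused 4 probes, a condition added after a wrong name was noticed. All 523 symbols of the gene lists were found in the table, 5 under a current symbol.

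All 12 arrays were fitted together in limma 3.58.1 (R 4.3.3) with 4 group means and empirical Bayes moderation; the residual degrees of freedom were 8 and the prior ones 3.21, 2.16 and 2.15 in the order of the comparisons. The comparisons were Tbx3-high minus Tbx3-low mESC, null-labelled minus wild-type iPSC, and the difference between (high minus low) and (wild type minus null). mESC and iPSC lay on separate slides, so they were not compared directly. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called passed, risen or fallen. Where 1 group was dim for a probe, the fold is a lower bound and is written "at least". It takes each array of that group at its own signal or at the lowest signal well above background on that array, whichever was higher. Genes dim in a group for the difference, and Bmp2, Psmb8 and Nefm, dim on part of a group's spots, were also given with each signal no lower than that lowest signal of its array, a step added after the values were seen. Signals were tabulated in Python 3.11.15 (pandas 2.3.3) and drawn with matplotlib 3.10.9. The correlation across genes was tested by an exact permutation over the 70 regroupings of the mESC arrays into 4 and 4.

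Before the data were examined, 25 gene lists were fixed from general knowledge: naive pluripotency, general pluripotency, formative and primed epiblast, primitive endoderm, primitive streak and mesendoderm, neuroectoderm, trophectoderm, two-cell-like state, germ cell and meiosis, Wnt targets, FGF-ERK targets, Nodal-Activin targets, BMP targets, DNA methylation, imprinted genes, T-box family, fibroblast (feeder) markers, endothelial and blood markers, p53 targets, cell cycle, immediate early and heat shock, glycolysis and hypoxia, oxidative phosphorylation, extracellular matrix and adhesion, and X and Y transcripts. Tbx3 was left out of each list, and some genes are in more than 1 list. Lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation and fry were alternatives. Camera asks whether a list's genes shift relative to all other genes. Fry asks another question, whether a list's genes move on balance one way, without regard to other genes. A list that passed fry alone may therefore move no more than genes at large. Missing values were filled for these tests, 15 in the mESC and 16 in the iPSC comparison. The genes to name were also fixed then: Tbx3; the 12 largest rises and falls of each main comparison by fitted change among genes that passed and whose groups did not overlap, without clone or predicted names; the 5 largest each way for the difference; up to 4 members per list with the smallest adjusted p; the 5 largest per combination of directions among genes passing in both; and Pou5f1, Sox2, Nanog, Klf4, Dppa3, Tbx2, Gata6, Gata4, Sox17, Fgf5, T, Sox1 and Cdx2. Of the list members and of the genes passing in both, the text prints a part, chosen for space after their values were seen and leaving out those whose call ended with 1 array left out. Of the largest rises and falls, 2 genes are not reported here.

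The alternatives fixed before the data were examined were quantile normalization, normexp background correction with an offset of 50, the series table's values, no filter on dim probes, only probes well above background on all 12 arrays, outlier spots kept, the mean of a gene's probes, each probe tested by itself, each comparison fitted on its own arrays, a trended and robust prior, array weights, the replicate number as a block, the slide row as a block, a minimum change of 1, an adjusted p under 0.01, and each array left out in turn with the same genes. Fits on the mESC arrays of slide row 1 or slide row 2 alone were added after seeing the data. On the mESC slide, same-numbered arrays deviated together from their group means (r = 0.140, 0.245, 0.173 and 0.109 for the 4 numbers, mean 0.166). Arrays of the same row with other numbers correlated at a mean of 0.181 and those of other rows at -0.173. For low replicates 1 and 4 the closest Tbx3-high array had another number. The values thus follow the slide row and do not show a pairing by number, and the labels give none. The replicate number as a block therefore served as an alternative only.

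The steps were tested on simulated data for the real genes. In the mESC comparison (15884 genes), 56.7%, 97.0% and 100% of genes changed by 0.5, 1 and 2 were recovered, and 7.46% of calls were false. In the iPSC comparison (17765 genes) these were 35.8%, 65.7% and 92.4%, with 5.67% false, and for the difference (17926 genes) 7.46%, 67.2% and 89.4%, with 8.26% false. A simulated list of 25 genes shifted by 0.5 had camera p-values of 3.3e-48, 5.6e-21 and 1.9e-22 in these comparisons, and an unshifted one 0.278, 0.279 and 0.655. Each simulation changed 67, 67 and 66 genes by 0.5, 1 and 2 and the 25 genes of the shifted list. The real comparisons called far more genes, 5487 in the mESC and 6753 in the iPSC. The adjusted p depends on the share of changed genes, so these rates do not carry over to the real comparisons. The noise of each simulated gene was independent. In the mESC comparison the estimated correlations of the real lists ran from -0.0586 (BMP targets) to 0.301 (primitive endoderm). The simulation therefore does not check camera on lists whose genes vary together. Replicate arrays correlated at 0.988 to 0.995 within groups, and the median standard deviation between arrays of the detected probes was 0.0915 to 0.129.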

Results

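Gene expression was measured on 12 one-colour Agilent arrays, 1 per sample, in mouse embryonic stem cells (mESC) and mouse induced pluripotent stem cells (iPSC). The mESC arrays held 4 samples labelled Tbx3-high and 4 labelled Tbx3-low. The iPSC arrays held 2 samples labelled Tbx3-null and 2 labelled wild type. Tbx3 encodes a T-box transcription factor of the pluripotency network. The 75th percentile of the probe signals lay between 314 and 458 on the mESC arrays and between 699.8 and 1007 on the iPSC arrays. The share of spots well above background was 55.9% to 64.8% on the mESC arrays. On the iPSC arrays it was 68.6% and 68.0% for the wild type and lower, 63.0% and 62.4%, for the null label. Whether this difference bears on the falls in the null-labelled arrays was not tested. Each array had 0 saturated spots. Changes are log2 differences between group means with the standard error (SE) of the limma fit, from 4 arrays per mESC group and 2 per iPSC group, and adjusted p-values are limma's with Benjamini-Hochberg adjustment. The number of arrays limits the precision. The labels do not say whether the arrays of a group came from separate cultures, so the p-values measure the spread between these samples.

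The Tbx3 level was read from the 1 Tbx3 probe on the array, on chromosome 5 from 120134511 to 120134570 (mm9). Tbx3 was 2.51-fold higher in the Tbx3-high than in the Tbx3-low mESC, a change of 1.33 ± 0.07 (SE, adjusted p = 1.9e-07), and all 4 Tbx3-high arrays lay above all 4 Tbx3-low arrays. In the iPSC, Tbx3 was not lower in the arrays labelled Tbx3-null: the null minus wild-type change was 0.32 ± 0.10 (SE, adjusted p = 0.030). That call ended without null replicate 1 (adjusted p = 0.114), null replicate 2 (0.0792) or wild-type replicate 1 (0.237), and the change itself ran from 0.145 to 0.503 as each iPSC array was left out. The call also ended under quantile normalization, with a change of 0.127 (adjusted p = 0.345), with the series table's values (0.180), without the dim filter (0.0512), on the iPSC arrays alone (0.169) and with the replicate number as a block (0.0586), and its adjusted p ranged from 0.00171 to 0.345 over the alternatives. The part of the gene removed in the null allele is not given in the sources used here, so this probe does not check the null label. The samples are therefore called arrays labelled Tbx3-null.

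**Figure D1:**
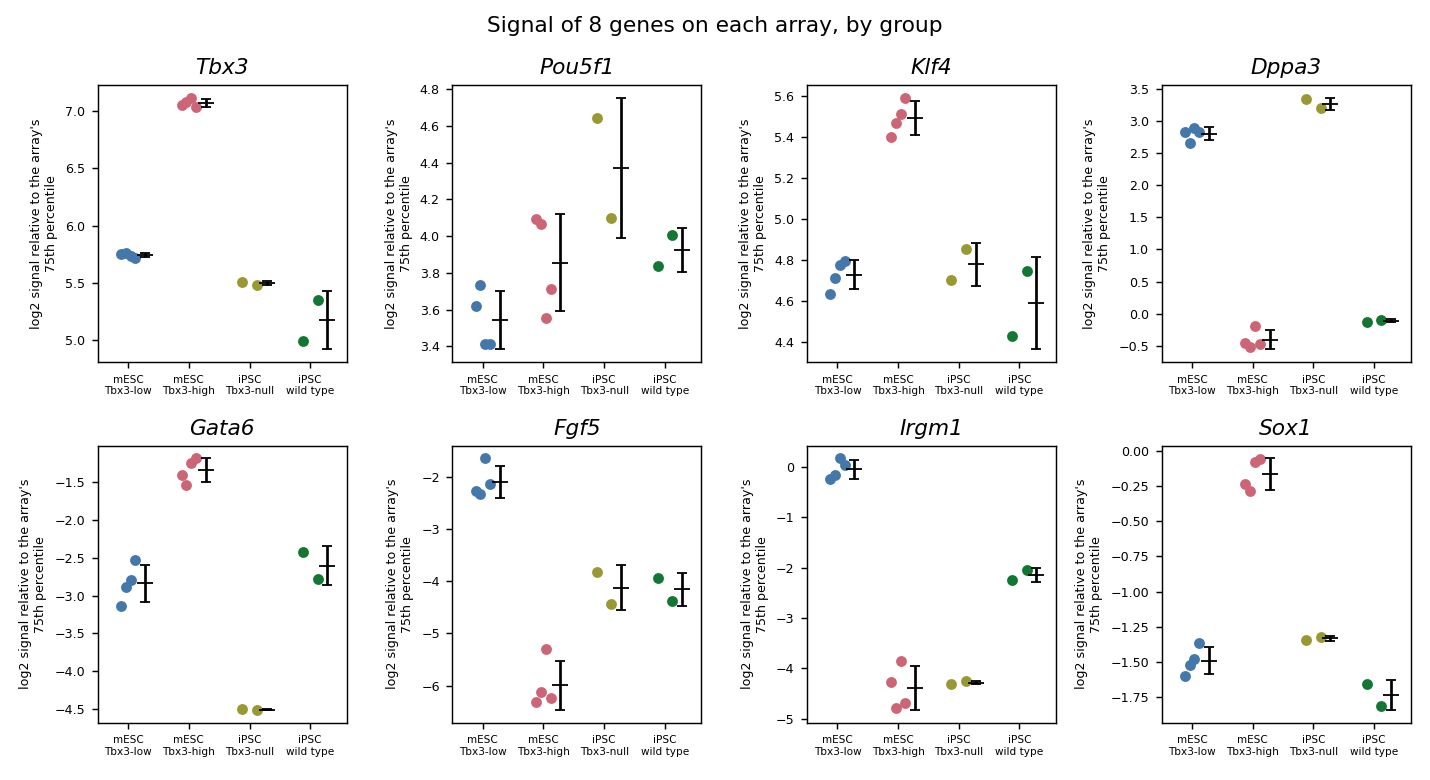
Signal of 8 genes on each of the 12 arrays, as log2 relative to the array's 75th percentile, with each group's mean and standard deviation (n = 4, 4, 2 and 2); the vertical axes differ in range between genes. Tbx3, Klf4, Gata6 and Sox1 were higher in the Tbx3-high than in the Tbx3-low mESC and Dppa3, Fgf5 and Irgm1 were lower, while Pou5f1 did not pass in either comparison.

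The first comparison asked which genes differed between mESC with a high and with a low Tbx3 level. In the Tbx3-high cells most markers of naive pluripotency rose, among them Klf4, a Krüppel-like factor of the naive network, by 0.76 ± 0.08 (SE, adjusted p = 2.7e-05). Most markers of the later epiblast fell, with Fgf5, a growth factor of the post-implantation epiblast, at least 7.18-fold lower. Gbp2, an interferon-inducible guanylate-binding GTPase, was at least 66.7-fold lower. Dppa3, a maternal and germ cell factor that shields DNA methylation, moved against most of the naive markers, at -3.21 ± 0.08 (SE, adjusted p = 1.0e-09).

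Among the 12 largest rises, Cdx1, a caudal homeobox factor, rose by 2.84 ± 0.10. Bmp2, a bone morphogenetic protein ligand, was not well above background on 3 of the 4 Tbx3-low arrays, and its rise was 1.76 with each signal no lower than the lowest one well above background on its array. Adcy2, an adenylyl cyclase, was at least 6.87-fold higher and Rapgef3, an exchange factor activated by cyclic AMP, rose by 2.30 ± 0.08. The inhibitory lymphocyte receptor Btla was at least 2.25-fold higher and the linker histone H1f0 at least 1.62-fold higher, both dim in the Tbx3-low cells. The citrate transporter Slc13a5 rose by 2.37 ± 0.13. Ky, a muscle-associated peptidase gene, rose by 2.47 ± 0.13, the homeobox gene Tlx2 by 2.41 ± 0.18, the doublecortin-like kinase Dclk3 by 2.40 ± 0.08 and the spinster family member Spns3 by 2.34 ± 0.15.

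Of the 12 largest falls, 6 were genes with known immune functions. Besides Gbp2, the oligoadenylate synthetase-like gene Oasl2 was at least 28.0-fold lower, the guanylate-binding GTPase Gbp3 at least 9.29-fold and the immune checkpoint ligand Cd274 at least 8.36-fold, all dim in the Tbx3-high cells. The immunity-related GTPase Irgm1 changed by -4.35 ± 0.18 and the immunoproteasome subunit Psmb8, not well above background on 2 of the 4 Tbx3-high arrays, by -3.82 with each signal no lower than the same limit. The other falls were Trim67, a tripartite motif protein (at least 14.7-fold lower), Tmem140 (at least 6.16-fold), Fgf5, the lysophosphatidic acid-producing enzyme Enpp2 (-4.34 ± 0.12), the iron exporter Slc40a1 (-3.85 ± 0.15) and the X-linked gene Fndc3c1 (-3.68 ± 0.09). Gbp family probes can also bind transcripts of related genes.

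Of the pluripotency and lineage factors fixed before the data were examined, Gata6, an endoderm factor, rose by 1.49 ± 0.13 (SE, adjusted p = 5.5e-06), Sox1, a neural factor, by 1.32 ± 0.08 (2.5e-07) and Sox17, an endoderm factor, by 0.57 ± 0.15 (0.011). The core factors did not pass: Pou5f1 was at 0.31 ± 0.15 (adjusted p = 0.131), Sox2 at 0.12 ± 0.07 (0.242) and Nanog at 0.12 ± 0.06 (0.143). Nanog passed with the mean of its probes (0.00402; range over the alternatives 0.00402 to 0.531), and 2 of its 3 probes passed by themselves, at 0.41 each (0.0347 and 0.00189). Pou5f1 passed with the slide row as a block (0.0418; range over the alternatives 0.0418 to 0.405). The other Sox1 probe was at 0.53 (0.233) and the other Sox17 probe at 0.40 (0.0723). The endoderm factor Gata4 was at 0.36 ± 0.14 (0.0718) and the mesoderm factor T at 0.62 ± 0.25 (0.0779). With the replicate number as a block, Gata4 and T passed (adjusted p = 0.0335 and 0.00605; ranges over the alternatives 0.0207 to 0.184 and 0.00605 to 0.453). Gata4 also passed with array weights (0.0422), with the slide row as a block (0.0207) and without low replicate 4 (0.0242) or high replicate 2 (0.0312), and T with the slide row as a block (0.0360) and without low replicate 1 (0.0266). Tbx2, a T-box factor, and Cdx2, a trophoblast factor, were not above background on all arrays of either group and were not tested.

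Of 15884 genes tested between the mESC groups, 5487 passed an adjusted p of 0.05, 3083 higher and 2404 lower in the Tbx3-high cells. The excess of higher genes depended on the scaling, with 2816 higher and 2914 lower under quantile normalization and 2504 and 2703 with the series table's values. At least 2-fold changes were found for 303 and 429 of the 5487 genes. The array values of the groups did not overlap for 4924 of the 5487 genes. The Tbx3-low arrays lay in columns 1 and 2 of the slide and the Tbx3-high arrays in columns 3 and 4, so group and column are confounded.

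Of the 24 genes of the naive pluripotency list, all measured, 17 rose, 4 fell and 3 did not pass, and the counts adjusted over the list alone were the same. The list was shifted up (camera, adjusted p = 0.000762), but not with an estimated correlation (adjusted p = 0.504 with an estimated correlation). Besides Klf4, the adhesion molecule Jam2 rose by 1.64 ± 0.09, the homeobox gene Gbx2 by 1.10 ± 0.10 and the secreted phosphoprotein Spp1 by 1.0 ± 0.08. Of the 25 formative and primed epiblast genes, 15 fell, 7 rose and 3 did not pass, and 16 fell and 7 rose adjusted over the list alone. That list was shifted down (camera, adjusted p = 0.00326; adjusted p = 0.383 with an estimated correlation). The growth factor Fgf15 was at -1.36 ± 0.07, the kinase Pim2 at -1.47 ± 0.08 and the POU factor Pou3f1 at -0.96 ± 0.09.

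The germ cell and trophectoderm lists were also shifted down under camera, though not with an estimated correlation. Of 22 measured germ cell and meiosis genes, 12 fell, 2 rose and 8 did not pass, the same adjusted over the list alone, and the list was shifted down (camera, adjusted p = 0.000999; adjusted p = 0.302 with an estimated correlation). The X-linked reproductive homeobox genes Rhox6 and Rhox9 were at -3.45 ± 0.08 and -3.40 ± 0.15, and the meiotic chromosome protein Sycp3 at -0.75 ± 0.08. Of 18 measured trophectoderm genes, 8 fell, 3 rose and 7 did not pass, the same adjusted over the list alone (camera, adjusted p = 0.00326, down; adjusted p = 0.302 with an estimated correlation). The keratin Krt18 was at -1.72 ± 0.11, the trophoblast factor Gata3 at -1.57 ± 0.08 and the AP-2 factor Tfap2c at -1.40 ± 0.08. These were the 4 lists that passed camera between the mESC groups. As many or more came from 3 of the 35 splits of the 8 arrays into equal groups, the real one included. The others of these kept 3 of the 4 Tbx3-low arrays together, so they carry part of the group difference.

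Markers of other lineages went both ways, and their lists did not pass camera. With fry in place of camera, primitive endoderm (adjusted p = 0.00394, up), primitive streak and mesendoderm (1.5e-06, up) and general pluripotency (0.0244, down) passed. Of 28 primitive endoderm genes, 11 rose, 3 fell and 14 did not pass (13 and 4 adjusted over the list alone; camera, adjusted p = 0.109), with the basement membrane collagens Col4a1 at 1.86 ± 0.10 and Col4a2 at 1.75 ± 0.14 and the activin inhibitor Fst at 1.26 ± 0.09. This list passed without high replicate 2 (adjusted p = 0.0301; range over the alternatives 0.00394 to 0.885). Of 17 primitive streak and mesendoderm genes, 5 rose, 2 fell and 10 did not pass, with the T-box factor Eomes at 1.39 ± 0.10 and the homeobox gene Evx1 at least 1.91-fold lower (camera, adjusted p = 0.304). Of 16 neuroectoderm genes, 6 rose, 4 fell and 6 did not pass (6 and 5 adjusted over the list alone; camera, adjusted p = 0.740), with the intermediate filament genes Ina at -1.39 ± 0.07 and Nes at -1.45 ± 0.11. Of 20 general pluripotency genes, 2 rose, 5 fell and 13 did not pass, with the Myc family factor Mycn at -1.0 ± 0.11 (camera, adjusted p = 0.323). Of 17 genes of the two-cell-like state, 1 rose, 2 fell and 14 did not pass (camera, adjusted p = 0.695), the riser being Tmem92 at 1.02 ± 0.09. For the streak, general pluripotency and two-cell-like lists the counts adjusted over the list alone were the same.

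Signalling target lists held genes that moved both ways, and none passed camera. With fry, Nodal-Activin targets (adjusted p = 0.000948, down), BMP targets (0.00169, up) and Wnt targets (0.0449, up) passed. Of 12 Nodal-Activin targets, 6 fell, 4 rose and 2 did not pass (camera, adjusted p = 0.285), with the feedback inhibitors Lefty1 at -3.00 ± 0.12 and Lefty2 at -1.18 ± 0.08. Of 15 FGF-ERK targets, 7 rose, 4 fell and 4 did not pass (7 and 5 adjusted over the list alone; camera, adjusted p = 0.75), with the feedback inhibitor Spry2 at 1.07 ± 0.12 and the ETS factor Etv4 at 1.13 ± 0.17. Of 10 BMP targets, 4 rose, 1 fell and 5 did not pass (camera, adjusted p = 0.537), with the helix-loop-helix inhibitors Id3 at 0.77 ± 0.08 and Id2 at -1.64 ± 0.10. Of 18 Wnt targets, 6 rose, 4 fell and 8 did not pass (7 and 7 adjusted over the list alone), with Cdx1 the largest rise and the planar polarity gene Prickle1 at -1.34 ± 0.09. The Wnt list had a median of -0.03 and a mean of 0.18, and camera placed it down (adjusted p = 0.960). Of 11 T-box genes, 1 rose, 2 fell and 8 did not pass (camera, adjusted p = 0.815, down; median 0.02, mean -0.01), with Tbx4 at -1.66 ± 0.18. For the Nodal-Activin, BMP and T-box lists the counts adjusted over the list alone were the same.

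Of 29 measured imprinted genes, 6 rose, 8 fell and 15 did not pass (7 and 9 adjusted over the list alone; camera, adjusted p = 0.740, down; median 0.03, mean -0.16). The growth-restraining transcript H19 was at -3.29 ± 0.27 and the zinc finger gene Plagl1 at 1.20 ± 0.11. Of 18 DNA methylation genes, 4 rose, 4 fell and 10 did not pass (5 and 4 adjusted over the list alone; camera, adjusted p = 0.695), with Zfp57, which maintains imprints, at 1.09 ± 0.12 and the methylcytosine oxidase Tet2 at 0.89 ± 0.10 (1 of its 3 probes was at 0.43, adjusted p = 0.152). Of 15 fibroblast (feeder) markers, 5 rose, 2 fell and 8 did not pass (5 and 3 adjusted over the list alone; camera, adjusted p = 0.537), with the growth factor receptor Pdgfrb at 1.83 ± 0.10, the collagen Col1a1 at 1.54 ± 0.10 and the smooth muscle protein Tagln at -1.36 ± 0.11. Of 9 endothelial and blood markers, 3 rose, 0 fell and 6 did not pass (median -0.11, mean 0.11, camera up, adjusted p = 0.859), with the blood factor Runx1 at 0.88 ± 0.11. Of 26 extracellular matrix and adhesion genes, 9 rose, 7 fell and 10 did not pass (camera, adjusted p = 0.75), with the basement membrane linker Nid1 at 1.77 ± 0.08 and the tight junction protein Cldn3 at -1.34 ± 0.09. For the endothelial and matrix lists the counts adjusted over the list alone were the same. With fry, DNA methylation (adjusted p = 0.0129, down), fibroblast markers (8.8e-06, up) and the matrix list (0.0298, up) passed. The DNA methylation list had a median of -0.08 and a mean of -0.11. Its member with the smallest adjusted p was Dppa3, which fell.

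None of the lists of general cell functions passed camera between the mESC groups. With fry, p53 targets (adjusted p = 0.0449, down), immediate early and heat shock genes (0.00145, down) and oxidative phosphorylation (0.0249, up) passed. Of 26 cell cycle genes, 6 rose, 3 fell and 17 did not pass (7 and 4 adjusted over the list alone; camera, adjusted p = 0.740), with cyclin E gene Ccne1 at -0.67 ± 0.07. Of 20 p53 targets, 3 rose, 6 fell and 11 did not pass (camera, adjusted p = 0.304), with the cyclin-dependent kinase inhibitor locus Cdkn2a at -0.94 ± 0.08. Of 21 immediate early and heat shock genes, 4 rose, 6 fell and 11 did not pass (camera, adjusted p = 0.304), with the zinc finger factor Klf6 at -0.71 ± 0.06. Of 27 glycolysis and hypoxia genes, 4 rose, 3 fell and 20 did not pass (3 and 3 adjusted over the list alone; camera, adjusted p = 0.75), with the glucose transporter Slc2a3 at 0.42 ± 0.08. Of 28 oxidative phosphorylation genes, 5 rose, 1 fell and 22 did not pass (camera, adjusted p = 0.259). Of 4 X and Y transcripts measured, 1 rose and 3 did not pass; the list was too short for a set test, and the riser was the Y-linked helicase gene Ddx3y at 0.37 ± 0.07, which did not pass on slide row 1 alone (adjusted p = 0.0539; range over the alternatives 0.000668 to 0.0539). For the p53, immediate early, oxidative phosphorylation and X and Y lists the counts adjusted over the list alone were the same.

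**Figure D2:**
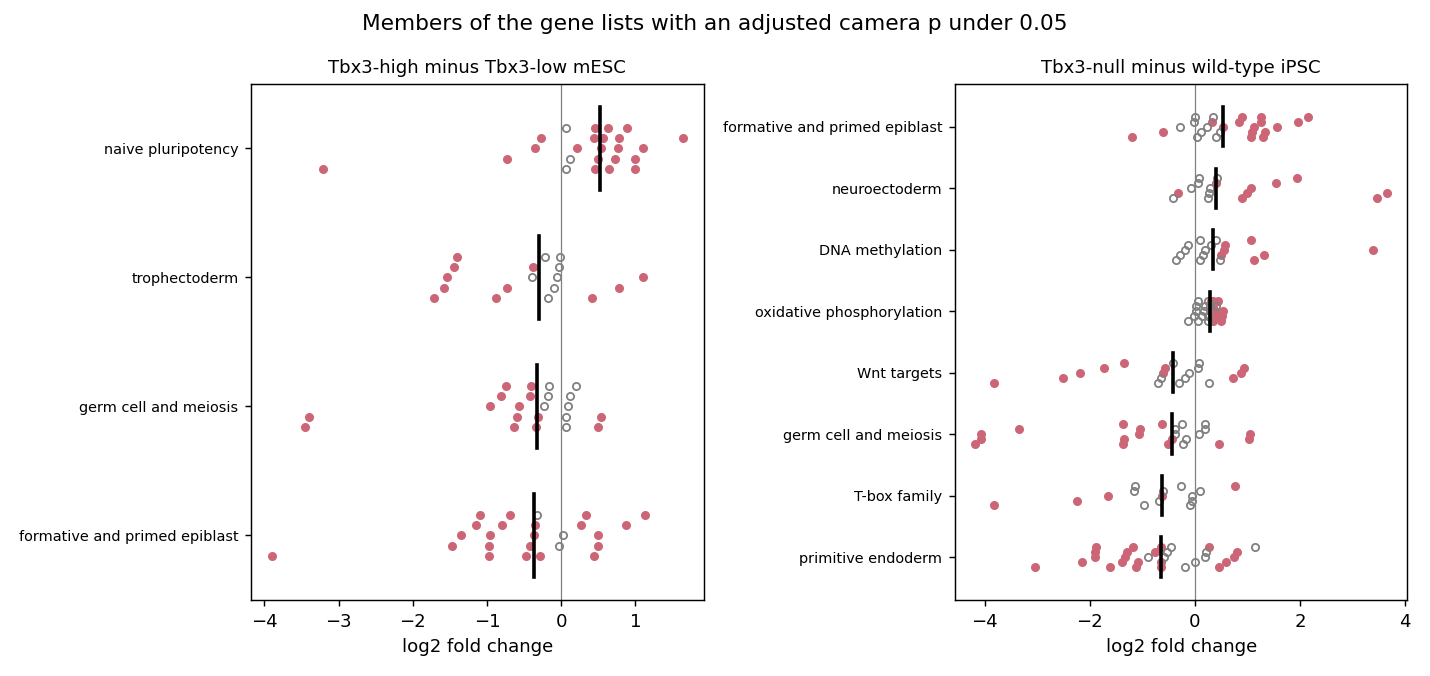
Log2 fold change of each measured member of the 4 lists that passed camera between the mESC groups and of the 8 lists that passed between the iPSC groups; filled points passed an adjusted p of 0.05, open points did not, and bars mark list medians. The median of the naive pluripotency list lay above 0 in the Tbx3-high cells, and that of the formative and primed epiblast list lay below 0 in them and above 0 in the arrays labelled Tbx3-null, with members on both sides; no list passed with an estimated correlation.

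The second comparison asked which genes differed between iPSC labelled Tbx3-null and wild-type iPSC. In the arrays labelled Tbx3-null, X-linked genes of the Xlr family and several germ cell genes were far lower: Xlr5b, an X-linked lymphocyte-regulated gene, was at least 352-fold lower. The primitive endoderm list was shifted down, with the endoderm factor Gata6 at -1.90 ± 0.19 (SE, adjusted p = 2.6e-05), and the formative epiblast and neuroectoderm lists were shifted up, with the intermediate filament gene Ina at 3.66 ± 0.09 (SE, adjusted p = 1.8e-09). None of these lists passed with an estimated correlation. Dppa3, the maternal and germ cell factor, rose by 3.38 ± 0.12 (SE, adjusted p = 1.8e-08).

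Ubd, a ubiquitin-like protein gene, was at least 391-fold higher. Also far above the wild type were Lrrc6, a factor for ciliary dynein assembly (at least 48.2-fold), Crisp1, a cysteine-rich secretory protein of the male tract (at least 27.4-fold), Fam240b (at least 26.2-fold), the membrane protein Plppr1 (at least 8.68-fold) and the matrix protein Thbs2 (at least 4.85-fold), all dim in the wild type. The class I myosin Myo1f rose by 5.44 ± 0.11, the PDZ domain gene Pdzrn4 by 4.44 ± 0.40, Crisp3 by 4.39 ± 0.14 and the stress-response gene Gadd45g by 4.06 ± 0.11. The pigment cell receptor Gpr143 rose by 3.86 ± 0.30 and the WD repeat gene Wdr95 by 3.86 ± 0.27; the other Wdr95 probe was at 0.29 (adjusted p = 0.727).

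The nuclear receptor Nr1h5 was at least 487-fold lower. Xlr5c was at least 280-fold lower, the X-linked gene DXBay18 at least 144-fold, Xlr5a at least 68.5-fold and Xlr4b at -6.28 ± 0.13. The estrogen receptor Esr1 was at least 101-fold lower and the acute-phase protein Saa3 at least 94.0-fold. The homeobox genes Crxos and Obox6 were at -8.99 ± 0.13 and -5.64 ± 0.13, and the neurofilament gene Nefm, with part of its spots on the null-labelled arrays not well above background, at -6.07 with each signal no lower than the lowest one well above background on its array. Of the 3 Crxos probes, 1 did not change (-0.03, adjusted p = 0.910). Probes of the Xlr, Crisp and Zscan4 families can bind transcripts of near-identical relatives, so values of single members are uncertain.

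Of the fixed factors, T was at -3.83 ± 0.37 (SE, adjusted p = 2.2e-05), and Tbx2 was at least 1.51-fold lower (adjusted p = 0.00354), a call that ended under normexp background correction (0.397; range over the alternatives 0.00106 to 0.397). Sox17 was at -0.75 ± 0.21 (adjusted p = 0.018), Cdx2 at -1.64 ± 0.56 (0.040) and Sox1 at 0.40 ± 0.11 (0.014), but these calls depended on single arrays and on the processing. Sox17 did not pass under quantile normalization (0.0554; range over the alternatives 0.00533 to 0.121) or without null replicate 1 (0.0578), null replicate 2 (0.0806) or wild-type replicate 2 (0.121). Sox1 did not pass without the same arrays (0.0514, 0.0566 and 0.0912), with the mean of its probes (0.733) or on the iPSC arrays alone (0.0575; range over the alternatives 0.00286 to 0.733), and its other probe was at -0.14 (0.852). Cdx2 did not pass without any 1 of the 4 iPSC arrays (0.101 to 0.150), low replicate 1 (0.0537) or low replicate 4 (0.0502), nor under quantile normalization (0.0645) or without the dim filter (0.0622; range over the alternatives 4.3e-07 to 0.150). Pou5f1 at 0.45 ± 0.22 (0.137), Sox2 at 0.16 ± 0.10 (0.234), Nanog at 0.14 ± 0.08 (0.206), Klf4 at 0.19 ± 0.12 (0.230), Gata4 at -0.00 ± 0.21 (0.989) and Fgf5 at 0.03 ± 0.35 (0.955) did not pass. Pou5f1 passed without null replicate 2 (0.0437) and Klf4 without wild-type replicate 2 (0.0492).

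Of 17765 genes tested between the iPSC groups, 6753 passed, 3817 higher and 2936 lower in the arrays labelled Tbx3-null, with at least 2-fold changes for 713 and 1335. The excess of higher genes depended on the settings, with 3197 higher and 3177 lower under quantile normalization, 3378 and 3466 with the series table's values, and 2758 and 2807 on the iPSC arrays alone. With 2 arrays per group the spread came mostly from the pooled fit, and group and slide column were again confounded.

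The formative, neuroectoderm, DNA methylation and oxidative phosphorylation lists were shifted up under camera, though not with an estimated correlation. Of the 25 formative and primed epiblast genes, 14 rose, 2 fell and 9 did not pass (17 and 2 adjusted over the list alone; camera, adjusted p = 0.000458; adjusted p = 0.292 with an estimated correlation), with the surface antigen Cd24a at 1.56 ± 0.08, the kinase Pim2 at 1.29 ± 0.12, the methyltransferase Dnmt3b at 1.13 ± 0.12 and the helix-loop-helix factor Tcf15 at 1.09 ± 0.09. Of 17 measured neuroectoderm genes, 8 rose, 1 fell and 8 did not pass (camera, adjusted p = 0.00395; adjusted p = 0.292 with an estimated correlation), with the neurogenic factor Neurod1 at 1.94 ± 0.12 and the tubulin Tubb3 at 1.55 ± 0.12. Of 18 DNA methylation genes, 7 rose, 0 fell and 11 did not pass (camera, adjusted p = 0.0216; adjusted p = 0.406 with an estimated correlation), with the methyltransferase cofactor Dnmt3l at 1.08 ± 0.11 and the ubiquitin ligase Uhrf2 at 1.32 ± 0.11. The DNA methylation call ended under quantile normalization (adjusted p = 0.0725) and without null replicate 1 (0.0502; range over the alternatives 3.1e-05 to 0.406). Of 28 oxidative phosphorylation genes, 14 rose and 0 fell (16 and 0 adjusted over the list alone; camera, adjusted p = 0.00369; adjusted p = 0.406 with an estimated correlation), with the complex I subunit Ndufa1 at 0.53 ± 0.08. That call ended with the series table's values (0.571), quantile normalization (0.384) and normexp (0.0597; range over the alternatives 0.000695 to 0.571). For the neural and DNA methylation lists the counts adjusted over the list alone were the same.

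The primitive endoderm, germ cell, Wnt target and T-box lists were shifted down under camera, though not with an estimated correlation. Of 30 measured primitive endoderm genes, 16 fell, 5 rose and 9 did not pass, the same adjusted over the list alone (camera, adjusted p = 0.000857; adjusted p = 0.406 with an estimated correlation), with the transcriptional cofactor Cited1 at -2.16 ± 0.13 and the laminin Lama1 at -1.29 ± 0.13. Of 23 germ cell and meiosis genes, 12 fell, 3 rose and 8 did not pass (13 and 3 adjusted over the list alone; camera, adjusted p = 0.000458; adjusted p = 0.292 with an estimated correlation), with the germ cell RNA-binding protein Dazl at -4.07 ± 0.15, the germ cell surface protein Tex101 at -4.18 ± 0.25, the synaptonemal protein Sycp1 at -3.35 ± 0.17 and the meiotic gatekeeper Stra8 at -1.37 ± 0.12. Of 19 Wnt targets, 7 fell, 3 rose and 9 did not pass (8 and 4 adjusted over the list alone; camera, adjusted p = 0.0424; adjusted p = 0.406 with an estimated correlation), with the secreted inhibitor Wif1 at -2.51 ± 0.13 and the ubiquitin ligase Rnf43 at -1.72 ± 0.13. The Wnt call ended under quantile normalization (0.0725), with only probes well above background on all 12 arrays (0.104), with the mean of a gene's probes (0.0524) and without null replicate 1 (0.0609) or wild-type replicate 2 (0.107; range over the alternatives 0.000118 to 0.406). Of 15 T-box genes, 4 fell, 1 rose and 10 did not pass, the same adjusted over the list alone (camera, adjusted p = 0.0354; adjusted p = 0.292 with an estimated correlation), with Eomes at -1.66 ± 0.15. The T-box median was -0.63, or -0.26 with dim genes at their bound, and the call ended under quantile normalization (0.152), normexp (0.142), with the series table's values (0.113), with only probes well above background on all 12 arrays (0.367) and without null replicate 1 (0.102) or wild-type replicate 1 (0.0987; range over the alternatives 0.000258 to 0.367). These were the 8 lists that passed camera.

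The other lineage lists did not pass camera in the iPSC. With fry, general pluripotency (adjusted p = 0.000604, up), primitive streak and mesendoderm (4.3e-05, down), the two-cell-like state (0.0216, up), fibroblast markers (2.3e-05, down) and endothelial and blood markers (0.00718, down) passed. Of 24 naive pluripotency genes, 5 rose, 8 fell and 11 did not pass (5 and 9 adjusted over the list alone; camera, adjusted p = 0.305), with Klf5 at -0.85 ± 0.10. Of 20 general pluripotency genes, 6 rose, 0 fell and 14 did not pass (camera, adjusted p = 0.149), with Mycn at 1.5 ± 0.17 and the RNA-binding protein Lin28a at 0.75 ± 0.12. Of 15 primitive streak and mesendoderm genes, 2 rose, 6 fell and 7 did not pass (3 and 6 adjusted over the list alone; camera, adjusted p = 0.0958). The streak list passed without wild-type replicate 1 (0.0464; range over the alternatives 4.3e-05 to 0.812). Of 19 trophectoderm genes, 7 rose, 7 fell and 5 did not pass (8 and 7 adjusted over the list alone; median 0.09, mean -0.38, camera down, adjusted p = 0.895), with the AP-2 factor Tfap2a at -2.56 ± 0.24 and the galectin Lgals3 at 1.47 ± 0.10. Of 21 genes of the two-cell-like state, 8 rose, 2 fell and 11 did not pass (camera, adjusted p = 0.0958), with the zinc finger gene Zscan4a at 1.77 ± 0.16 and Pramel7 and Pramel6, of a leucine-rich repeat family, at -4.71 ± 0.17 and -3.64 ± 0.23. Of 18 fibroblast (feeder) markers, 5 rose, 5 fell and 8 did not pass (median 0.02, mean -0.21, camera down, adjusted p = 0.305), with Pdgfrb at -2.22 ± 0.14 and Col1a1 at -2.32 ± 0.15. Of 12 endothelial and blood markers, 2 rose, 3 fell and 7 did not pass (2 and 4 adjusted over the list alone; camera, adjusted p = 0.305), with Runx1 at -1.06 ± 0.16. For the general pluripotency, two-cell-like and fibroblast lists the counts adjusted over the list alone were the same.

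Of 16 FGF-ERK targets, 8 fell, 2 rose and 6 did not pass (camera, adjusted p = 0.0673), with the feedback inhibitors Spry2 at -1.82 ± 0.17 and Spry4 at -1.04 ± 0.12. That list passed without wild-type replicate 1 (0.0331; range over the alternatives 0.000771 to 0.406). Of 12 Nodal-Activin targets, 4 rose, 3 fell and 5 did not pass (camera, adjusted p = 0.917), with Lefty1 at 1.09 ± 0.18. Of 12 BMP targets, 3 rose, 4 fell and 5 did not pass (4 and 4 adjusted over the list alone; camera, adjusted p = 0.895), with Id2 at 1.18 ± 0.15. Of 20 p53 targets, 3 rose, 3 fell and 14 did not pass (median 0.09, mean -0.14, camera down, adjusted p = 0.917), with the apoptosis gene Pmaip1 at -1.87 ± 0.11. Of 27 cell cycle genes, 5 rose, 1 fell and 21 did not pass (camera, adjusted p = 0.647), with Ccne1 at 0.71 ± 0.09. Of 20 immediate early and heat shock genes, 4 rose, 4 fell and 12 did not pass (median 0.03, mean -0.06, camera down, adjusted p = 0.895), with Klf6 at 1.38 ± 0.08 and the stress factor Atf3 at -1.32 ± 0.12. Of 27 glycolysis and hypoxia genes, 4 rose, 3 fell and 20 did not pass (camera, adjusted p = 0.969), with the hypoxia-induced gene Ndrg1 at 1.67 ± 0.23. Of 26 extracellular matrix and adhesion genes, 2 rose, 7 fell and 17 did not pass (camera, adjusted p = 0.299), with Nid1 at -2.09 ± 0.11 and the tight junction protein Ocln at -1.61 ± 0.19. Of 7 X and Y transcripts, 0 rose, 0 fell and 7 did not pass (camera, adjusted p = 0.686). Apart from the BMP list, the counts adjusted over the list alone were the same in these lists. With fry, FGF-ERK targets (adjusted p = 0.000771, down) and the matrix list (0.0235, down) passed.

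Of 31 measured imprinted genes, 11 rose, 7 fell and 13 did not pass, the same adjusted over the list alone (camera, adjusted p = 0.686; with fry 0.0251, up). The paternally expressed zinc finger gene Peg3 rose by 3.36 ± 0.20 and the placental growth regulator Phlda2 by 2.69 ± 0.26, while Plagl1 was at -1.83 ± 0.16 (1 of its 4 probes was at -0.23, adjusted p = 0.385) and the decarboxylase gene Ddc at -1.68 ± 0.09. The arrays labelled Tbx3-null differed from each other at the Meg3 domain, an imprinted cluster of noncoding transcripts whose genes were chosen for mention after their values were seen. The 3 Meg3 probes were lower in null replicate 2 than in null replicate 1, at -4.22, -7.45 and -8.51. Those at -4.22 and -7.45 were not well above background in null replicate 2, so the size of their falls is uncertain. The Meg3 change between the groups, -4.75 ± 1.89 (SE, adjusted p = 0.073), did not pass.

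**Figure D3:**
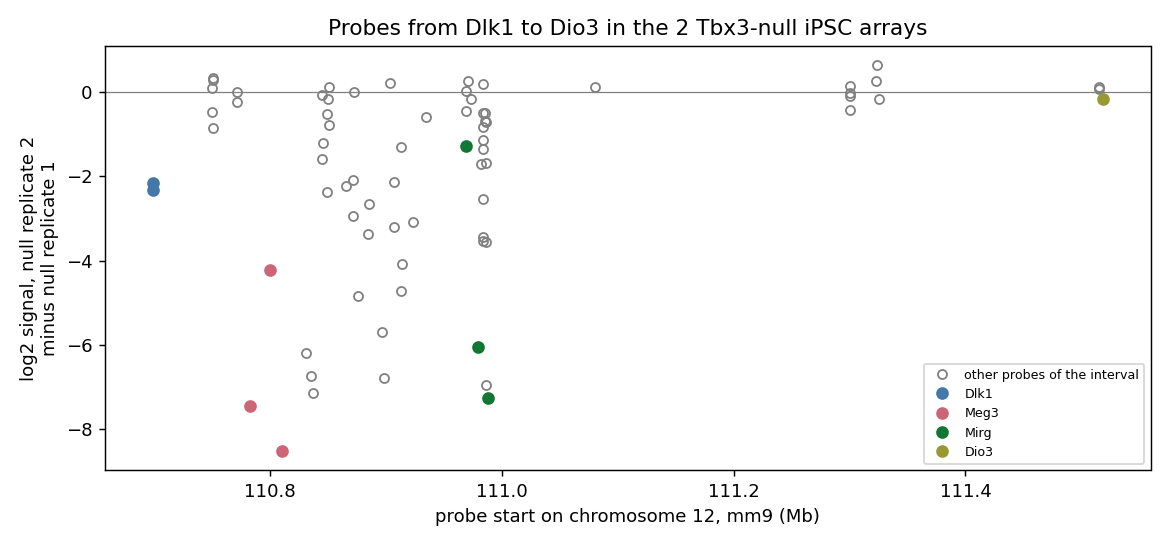
Log2 signal of null replicate 2 minus null replicate 1 for the probes between Dlk1 and Dio3 (chromosome 12, mm9, 110698502 to 111518851), by probe start in Mb. The Meg3 probes lie between -4.22 and -8.51, while the Dio3 probe lies at -0.17. Signals are drawn as they stand, and the Meg3 probes at -4.22 and -7.45 were not well above background in null replicate 2.

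The third comparison asked whether a higher Tbx3 level in mESC and the wild-type label in iPSC went with the same changes. Taken as (high minus low) minus (wild type minus null), the difference was 7.05 ± 0.14 for Myo1f and -8.71 for Crxos. Ubd, Nr1h5, Xlr5b and Saa3 were dim in 1 iPSC group, and with each signal no lower than the lowest one well above background on its array their differences were 8.03, -9.31, -8.64 and -6.49. Fam240b, Lrrc6, Plppr1 and Esr1, also among the largest differences, were not tested between the mESC groups. Their fitted differences, given with the flagged results, therefore do not measure a difference of effects. Among the fixed factors, the mESC and iPSC comparisons differed for Tbx3 itself (1.65 ± 0.13), Sox1 (1.72), Klf4 (0.95) and T (-3.21). They also differed for Fgf5, dim in the Tbx3-high cells (-2.81 with each signal no lower than that limit). Cell type and the kind of grouping, by Tbx3 level or by null label, change together here and cannot be told apart. Tbx2 and Cdx2 were not tested between the mESC groups, so their fitted differences, also given with the flagged results, do not measure a difference of effects either. Dppa3 fell with more Tbx3 in mESC and was lower in wild-type than in null-labelled iPSC, and its difference of 0.17 (adjusted p = 0.416) did not pass; neither did that of Gata6 at -0.41 (0.208). The Dppa3 difference passed under normexp (0.0324) and with the series table's values (0.0494). The difference did not pass for Pou5f1 at 0.76 (0.0518), Sox2 at 0.28 (0.110), Nanog at 0.26 (0.0679), Gata4 at 0.35 (0.327) or Sox17 at -0.18 (0.645). Nanog passed with the mean of its probes (0.00656; range over the alternatives 0.00656 to 0.840). Pou5f1 passed under normexp (0.0382), with only probes well above background on all 12 arrays (0.0319), with a trended and robust prior (0.0330), with the replicate number (0.0408) or the slide row (0.0136) as a block, and without low replicate 2 (0.0494), high replicate 3 (0.0287) or null replicate 2 (0.0206; range over the alternatives 0.0136 to 0.234). Of 17926 genes tested, the difference passed for 5961, positive for 3464 and negative for 2497, against 2588 and 2804 under quantile normalization and 2704 and 3022 with the series table's values.

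Among 15723 genes tested in both comparisons, 2925 passed in both, and 2046 of these (69.9%) moved the same way with a higher Tbx3 level and with the wild-type label. Genes higher in both numbered 1033, where independent lists would share 506.2, and genes lower in both numbered 1013, against 559.5. Genes higher with Tbx3 and lower in the wild type numbered 510, against 726.3, and the reverse 369, against 389.9. Among the largest changes per combination, the lymphocyte gene Cd3d (1.97 ± 0.12 in mESC), Nefm (0.83 ± 0.07) and the prostaglandin synthase Ptgs1 (1.36 ± 0.10) were higher in both. Dppa3, Gadd45g (-1.88 ± 0.08 in mESC), the vitamin C transporter Slc23a1 (-2.72 ± 0.20) and Fndc3c1 were lower in both. Myo1f (1.62 ± 0.08 in mESC), the adenylyl cyclase Adcy1 (1.15 ± 0.17) and the ubiquitin ligase scaffold Cul9 (1.04 ± 0.20; its other probe did not pass in either comparison, at -0.22 in mESC, adjusted p = 0.570) were higher with Tbx3 and lower in the wild type, and Irgm1 (-2.13 ± 0.27 in the null-labelled arrays) was lower with Tbx3 and higher in the wild type. Across the 15723 genes, which are not independent replicates, the changes correlated at r = 0.266 and rho = 0.242, with exact two-sided permutation p = 0.0571 and 0.143 over 70 regroupings of the mESC arrays, the smallest possible being 0.0286. The correlation passed without high replicate 1, 2 or 4 (r = 0.256, 0.261 and 0.264, exact permutation p = 0.0286, the smallest possible).

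**Figure D4:**
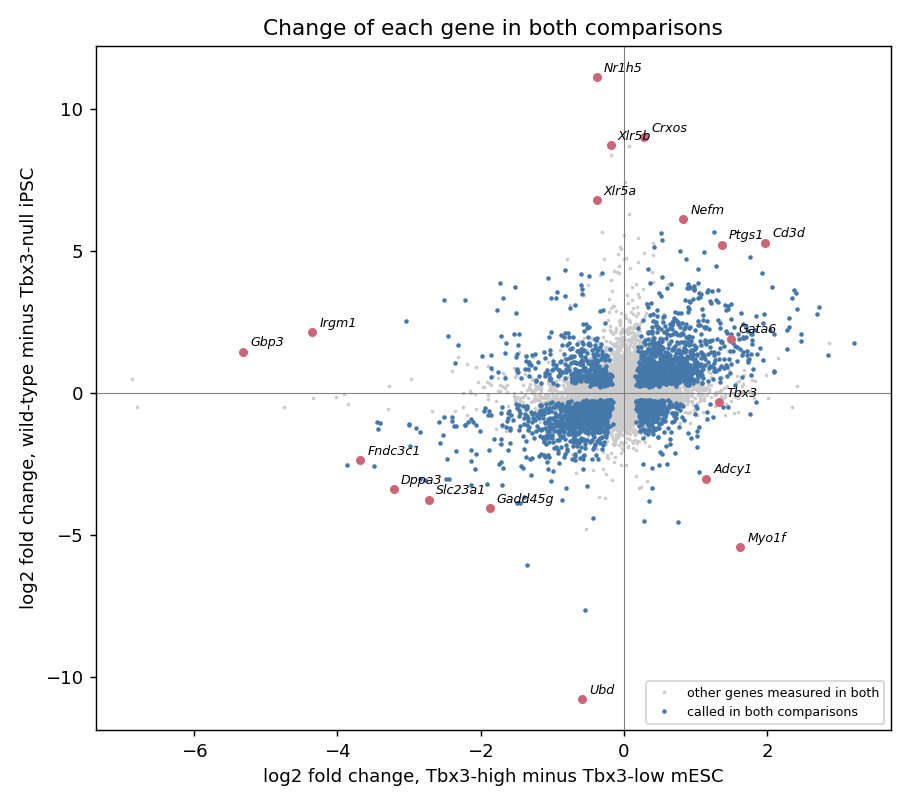
Log2 fold change of each gene in Tbx3-high minus Tbx3-low mESC (horizontal) and in wild-type minus null-labelled iPSC (vertical); blue points passed in both comparisons and named red points are genes of the text or of the naming rule. Of the 2925 genes that passed in both, 2046 lie in the upper right or lower left quadrant, with Gata6 in the upper right and Dppa3 in the lower left.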

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

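Of the tests in this part, those of chance, of a wrong sample and the first one of an array fault were fixed before their result was seen; those of slide column, slide row, fibroblasts, interferon genes, the Tbx3 level in both cell types and genome position were chosen after. The interferon explanation was reworded and given its Fisher test after the median had been seen, and the position test after the first array test had come out undecided. Setting dim genes at their bound in the test of the Tbx3 level, and leaving the 6 domain genes out of the position test, were also chosen after.

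The number of genes changed between Tbx3-high and Tbx3-low mESC was set against other splits of the same arrays. Of the 35 splits of the 8 arrays, 1, the real one with 5487 genes, gave as many genes, the highest other being 70. Among the 8 splits that part all same-numbered arrays the highest other was 0. The other splits mix Tbx3-high and Tbx3-low arrays, so the group difference widens their spread and lowers their counts. The real grouping thus stands apart from the other splits, but chance differences between cultures are not excluded. The split by slide row gave 70 genes, and the count was 6290 with slide row as a block. Each slide row held Tbx3-low and Tbx3-high arrays in equal number, so the design itself kept the row from producing the group difference. An effect of the slide column common to both slides is argued against by the genes passing in both comparisons. Only 30.1% of them moved the same way from columns 1 and 2 to columns 3 and 4. A column effect of the mESC slide alone cannot be told apart from the groups. For the 4 lists that passed, 3 of the 35 splits gave as many or more, the highest other giving 5 and the split by slide row 1. The others with 4 or 5 lists kept 3 of the 4 Tbx3-low arrays together, so they carry part of the group difference. This count therefore cannot decide whether chance gives as many lists, and chance is not excluded.

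The 6 immune effector genes lower in the Tbx3-high mESC (Gbp2, Gbp3, Oasl2, Irgm1, Psmb8 and Cd274) form the second pattern. Fibroblasts in the Tbx3-low samples would lower the fibroblast list in the Tbx3-high cells, but the median of its measured genes was 0.30. Between low and high, Fn1 and Col1a1, abundant in fibroblasts, went from 6.23 to 7.09 and from -2.23 to -0.70 (log2 relative to the 75th percentile). Tagln went the other way, from 2.04 to 0.68. The arrays do not separate changes of the stem cells themselves in these genes from signal of fibroblasts, so fibroblasts in the Tbx3-low samples are not excluded. The 37 other measured genes of a type I and a gamma interferon list had a median of -0.39. The 6 were picked from the largest falls of all tested genes, so other interferon genes had to fall less by that choice. This median therefore cannot decide whether all interferon genes fell as much as the 6. Of the 37, 21 (56.8%) fell, against 15.0% of all other genes (Fisher's exact test, p = 5.85e-09). That p is too small to the extent that these genes are regulated together. The lists were also drawn up after the fall of the 6 was seen. With these limits, the share goes with a downward shift of interferon-responding genes as a set. The same action of Tbx3 in both cell types cannot be told apart from its absence: with dim genes at their bound the median was -0.42 for the 4 of the 6 genes measured in the iPSC, which went both ways (-2.13 to 0.50); Irgm1 fell, the fall of Gbp3 was -0.34 at its bound and did not pass under normexp (adjusted p = 0.618) or with the series table's values (0.0922), and Gbp2 and Oasl2 did not pass. What set the interferon genes apart between the mESC groups, including the Tbx3 level itself, stays open.

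Of 73 probes between Dlk1 and Dio3 detected in null replicate 1, 14 (19.2%) were 16-fold or more lower in null replicate 2. Among them were the 3 of Meg3 (-8.51, -7.45, -4.22) and 2 of the 3 of Mirg (-7.25 and -6.05, the other at -1.28), genes chosen after their values were seen. The counts take signals as they stand, also below -5.25, the lowest signal well above background in null replicate 2. At that limit the Meg3 probe at -4.22, with a signal of -1.88 in null replicate 1, does not reach a 16-fold fall. The counts and tests were not repeated at that limit. Without the probes of the 6 domain genes first looked at, 9 of 64 (14.1%) were 16-fold or more lower, against 0.222% of probes elsewhere (Fisher's exact test, p = 5.63e-14, neighbouring probes not being independent). With signals as they stand, this argues against spots lost irrespective of position. The share over all probes outside the domain's genes, 0.248%, lay between the bounds set for and against an array fault and by itself decided nothing. Among 269 genes at least 8-fold apart between null replicate 1 and wild-type replicate 1, 95.5% lay closer to null replicate 1 in null replicate 2. This argues against a wild-type sample under that label. A different null-labelled sample could give the same result, so it is not excluded. The labels name no clone, so no biological explanation was tested.

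The effects of Tbx3-high against low and of wild type against null differed, by the test of the difference itself, for Tbx3 (1.65), Klf4 (0.95), T (-3.21), Sox1 (1.72), Myo1f (7.05) and Crxos (-8.71). The fitted differences of Fgf5 (-3.87), Ubd (10.19), Nr1h5 (-11.50), Xlr5b (-8.90) and Saa3 (-8.61) hold a group near background, and with each signal no lower than the lowest one well above background on its array they were -2.81, 8.03, -9.31, -8.64 and -6.49. Tbx2 (-3.18), Cdx2 (-2.37), Fam240b (6.67), Lrrc6 (6.15), Plppr1 (5.02) and Esr1 (-9.13) were not tested between the mESC groups, so their fitted differences do not measure a difference of effects; with the same limit they were -0.67, -1.67, 4.73, 5.64, 3.13 and -6.64. Cdx2 also did not pass without any 1 of the 4 iPSC arrays (adjusted p = 0.0550 to 0.0774), and Tbx2 did not under normexp (adjusted p = 0.221; range over the alternatives 0.000441 to 0.221).

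Single arrays stood apart from the other 3 of their group for 8 of 192 groups of named genes, where chance alone, at 1 in 20 groups, gives about 9.6. Those values, as log2 relative to the 75th percentile, were -3.00 for Dclk3, -1.12 for Gata4 and -1.59 for Slc13a5 in low replicate 4, -7.40 for Gbp3 and -6.45 for Oasl2 in high replicate 1, 2.08 for Lefty2 and -4.70 for Trim67 in high replicate 2, and 0.94 for Tagln in high replicate 4.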

How the results depend on the processing

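All alternatives here were fixed before the data were examined, except the fits on 1 slide row, which were chosen after seeing the data. For Tbx3-high against low, 5487 genes passed; 732 with a minimum change of 1, 3506 at an adjusted p under 0.01, 3655 and 3396 on slide row 1 or 2 alone (fewer arrays), and 4738 to 5517 with 1 array left out. For null against wild type, 6753 passed; 2048 with a minimum change of 1 and 4957 to 6763 with 1 array left out. The difference of the contrasts passed for 5961; 2029 with a minimum change of 1, 3521 at an adjusted p under 0.01 and 4415 to 5723 with 1 array left out. Of these, 58.1% were positive, against 48.0% under quantile normalization and 47.2% with the series table's values; the cause was not tested. For Tbx3-high against low, 3083 genes were higher and 2404 lower, against 2816 and 2914 under quantile normalization and 2504 and 2703 with the series table's values. For null against wild type, 3817 were higher and 2936 lower, against 3197 and 3177 under quantile normalization, 3378 and 3466 with the series table's values and 2758 and 2807 on the iPSC arrays alone. Passing in both comparisons were 2925; 1890 and 1903 on slide row 1 or 2 and 2333 to 2660 with 1 array left out. Tbx3 in the mESC stayed at 1.25 to 1.35 under each setting (1.31 to 1.34 with 1 array left out). Tbx3 in the iPSC changed by 0.127 under quantile normalization (adjusted p = 0.345), 0.186 with the series table (0.180), 0.324 without the dim filter (0.0512) and 0.145 to 0.503 with 1 array left out (range of adjusted p 0.00171 to 0.345); the cause was not tested. Lists passing numbered 4 in the mESC and 8 in the iPSC; 0 and 0 with an estimated correlation, 16 and 16 with fry, 4 in the iPSC under quantile normalization, and 4 to 5 and 5 to 9 with 1 array left out. Wnt targets in the mESC turned from down to up under fry (adjusted p = 0.0449; range 0.0449 to 0.996). The correlation of 0.266 ran from 0.249 to 0.276 with 1 array left out and was 0.189 without the dim filter (exact permutation p = 0.0286). Where 1 array was left alone in a group, it was assumed to vary like the others.

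With the replicate number as a block, 5636, 6618, 5577 and 2881 genes passed in the comparisons in the order above, 4 and 8 lists passed, and Tbx3 was at 1.33 (adjusted p = 3.3e-05) and 0.324 (0.0586); the correlation of 0.266 had an exact permutation p = 0.25, where the smallest possible was 0.125. The iPSC arrays of 1 number correlated at 0.0313 and share only a number. Among named genes the block changed no other calls than those of Tbx3 in the iPSC (lost), Gata4 and T in the mESC (adjusted p = 0.0335 and 0.00605), Xlr5a and Xlr5b in the mESC (0.0619 and 0.0572, lost) and Pou5f1 and Slc23a1 in the difference (0.0408 and 0.0335). Of 229 results of named genes, 209 passed; 193 of these passed under each setting apart from the stricter thresholds, 16 did not under at least 1, 10 of the 20 others passed under at least 1, and 0 reversed. Of 49 list results, 12 passed, 0 of them under each setting, and 20 of the 37 others passed under at least 1. Fry, which asks another question than camera, gave such a call to 19 list results. Signal near background limits folds to bounds.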

Other observations

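In this part, the tests by chromosome and of the interferon lists were chosen after the results were seen.

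Genes on the X chromosome were over-represented among the larger falls. In the Tbx3-high mESC, 46 of 590 tested X-linked genes (7.80%) fell at least 2-fold, against 2.51% of other genes (Fisher's exact test, adjusted p = 2.19e-09 over the chromosomes), among them Rhox6 and Rhox9, homeobox genes of a reproductive cluster, at -3.45 and -3.40, and Fndc3c1 at -3.68. In the arrays labelled Tbx3-null, 81 of 665 X-linked genes (12.2%) fell at least 2-fold, against 7.32% of others (adjusted p = 3.26e-04), among them Xlr5b, Xlr5c, Xlr5a and Xlr4b. At least 2-fold rises there were 39 of 665 X-linked genes (5.86% against 3.93%, Fisher's exact test, adjusted p = 0.196). In the Tbx3-high mESC they were 4 of 590 (0.678% against 1.95%, adjusted p = 0.270). With respect to the Tbx3 labels, the mESC and the iPSC falls run opposite ways. Neighbouring genes of 1 cluster are not independent, and Rhox and Xlr probes can bind transcripts of near-identical relatives, so these p-values are too small to that extent. Chromosome 19 held more of the 2-fold rises in the null-labelled arrays (41 of 584 genes, 7.02% against 3.90%, adjusted p = 0.0103) and chromosome 2 fewer of the falls (75 of 1387, 5.41% against 7.68%, adjusted p = 0.0170).

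Interferon genes outside the 6 named ones, all chosen after values were seen, fell in the Tbx3-high mESC in both lists: 10 of 16 type I genes fell and 1 rose, and 11 of 21 gamma and antigen presentation genes fell and 3 rose. The antiviral enzyme Rsad2 was at -3.08 ± 0.22, the GTPases Gbp7 and Igtp at -2.93 ± 0.24 and -2.15 ± 0.18, the chemokine Cxcl10 at -2.47 ± 0.13, the nucleic acid sensor Zbp1 at -2.46 ± 0.12 and the interferon regulatory factor Irf1 at -1.76 ± 0.09. Against them, the pro-apoptotic gene Xaf1 was at 1.79 ± 0.11 and the class II chaperone Cd74 at 1.08 ± 0.11. In the iPSC, 17 of 38 interferon genes outside the 6 fell in the null-labelled arrays, 5 rose and 16 did not pass (median -0.35). Among them Zbp1 was at -1.99 ± 0.17 and Cxcl10 at 2.34 ± 0.20. Over all 17765 genes tested there, 2936 fell. A fall in the null-labelled arrays means a higher signal in the wild type. With respect to the Tbx3 labels, these falls therefore run opposite to those in the Tbx3-high mESC.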
